A study of Homo sapiens with 8 samples.

How the data were processed

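RNA was measured in the human myeloma lines ARP1 and H929, each as wild-type cells and as cells carrying a knockdown of YTHDF2, a reader protein that binds N6-methyladenosine (m6A) in mRNA. The labels describe 8 libraries, an input library and an anti-m6A immunoprecipitation library for each line and genotype. The table used here holds the 4 input libraries, and the 4 immunoprecipitation libraries were not analysed here. Each combination of line and genotype therefore had 1 library.

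Per the labels' protocols, libraries were made with an NEBNext Ultra RNA kit and sequenced on a NovaSeq instrument. Bowtie2 and SAMtools, with the GRCh38 (hg38) human assembly, are named in the submitters' processing notes without a role or version. The deposited values are FPKM, fragments per kilobase of transcript scaled to library size, per the file headers, with 1 column per library and no pooling. How the authors computed FPKM, how fragments of overlapping genes were assigned and whether strand was used are not given in the sources used here. Overlapping genes, genes joined by readthrough transcripts and near-identical gene copies are therefore uncertain throughout. Chromosome positions are those of the deposited table.

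The table lists 32847 Ensembl genes with their symbols. Gene types were taken from a RefSeq gene table by symbol, which matched 22385 genes directly and 1074 through an older symbol, and 9388 genes stayed unmatched. No 2 libraries held identical values. The columns carry no counts. In genes with 1 transcript and a length of 300 to 3000 bases, low values multiplied by gene length gathered at 1 step per library, between 37.65 and 40.15. Read as 1 fragment, that step means that a transcript of 1 kb at 1 FPKM rests on 24.9 to 26.6 fragments, a counting error of 19.4% to 20.0%. The window searched for the step was set after the values were seen. Intervals from this depth cover counting error alone.

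All comparisons used log2(FPKM + 1). A fold change on this scale understates the change of genes with low values. Genes with a mean of at least 1 FPKM over the 4 libraries were tested, 10724 in all, of which 9104 were annotated as protein coding. Knockdown was compared with wild type, and H929 with ARP1, in 1 linear model with line and genotype as terms. The model was fitted in limma 3.58.1 under R 4.3.3, using lmFit and eBayes with a mean-variance trend, and Benjamini-Hochberg adjustment at 5%. The cell line paired the libraries, since each knockdown library has a wild-type library of its own line. The model has 1 residual degree of freedom, so its p-values measure how alike the log2 ratios of the lines are. Nothing in the labels says that the libraries came from repeated cultures. Within a line no test was made, and genes at 2-fold or more were counted. Agreement between lines was described by correlations across genes, which are not independent replicates, and by the number of genes at 2-fold or more in both lines against the number that independent lists would share.

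The model was tested on simulated data for the knockdown comparison, with 10724 genes of which 200 were changed, in 10 runs. It recovered 14.6% of genes changed 2-fold and 94.1% of genes changed 4-fold, and 8.80% of its calls were false at a nominal 5%.

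In total 29 gene lists were written before the data were examined. Each was summarised by the number of measured members, the median log2 ratio in each line and the percentile of that median among 10000 random lists of equal size matched on expression. The 27 lists with enough measured members were tested with camera in limma, at a preset correlation of 0.01 between genes and with an estimated correlation. With an estimated correlation the test rests on the 1 residual degree of freedom. It could then hardly call any list, so a list not called by it is not argued against. For KEGG pathways, the annotation in the deposited table was used, and these tests were added after the data were seen. Line-specific genes were protein-coding genes at least 32-fold higher in wild-type cells of 1 line than of the other, after adding 0.1 FPKM to both, and with at least 5 FPKM in the higher library.

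Genes named in the text followed a rule set before the data were examined. It took YTHDF2, the followed genes STAT5A, MAP2K2, EGR1 and CDKN1A, and, for each comparison across lines, the 10 highest and 10 lowest protein-coding genes. These were ranked by the smaller of the absolute log2 ratios of the 2 lines, with the same sign in both and a mean of at least 5 FPKM. It also took the 5 highest and 5 lowest genes of each line alone and up to 4 members of each list. The text leaves some of these out. AL132780.3, TP53INP2, IGHA2, IGKC, FGFR3, NSD2, the variable genes IGKV1-6 and IGHV1-69, and MGMT were chosen after their values were seen.

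Alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 FPKM, median-of-ratios rescaling, quantile normalization, eBayes without a trend, a model without the block, other fold thresholds and, for lists, an estimated correlation. After the data were seen, subtraction of an ARP1 share from the library labelled H929 knockdown, a restriction to genes with similar wild-type levels and another split of the libraries were added. Where the subtraction gave a negative value, the gene was set to no expression, and its ratio is then a floor fixed by its wild-type H929 level. The planned comparisons of immunoprecipitated with input RNA were not run. Calculations outside R used Python 3.11.15 with numpy, pandas, scipy and matplotlib.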

Results

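The series measured RNA in cells of multiple myeloma, a cancer of antibody-secreting plasma cells, to ask how the transcriptome and its m6A marks differ when YTHDF2 is knocked down. YTHDF2 binds m6A-bearing mRNA and recruits the machinery that shortens poly(A) tails. Input RNA of ARP1 and H929, each as wild type and knockdown, is described here, with 1 library for each of the 4 groups. Library values summed to 268976 FPKM in wild-type ARP1, 284830 in ARP1 knockdown, 257890 in wild-type H929 and 265644 in the library labelled H929 knockdown. Between 24062 and 25297 of 32847 genes had a value above 0. There were no replicates within a group, so a difference within a line has no replicate check.

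YTHDF2 itself (ENSG00000198492, chromosome 1, 28736621 to 28769775, plus strand) was lower in the knockdown library of ARP1 and not in that of H929. In ARP1 it stood at 3.17 FPKM in wild type, and knockdown held 31.6% of that level. In H929 it stood at 4.62 FPKM in wild type and 5.80 FPKM in the library labelled knockdown, a ratio of 1.26. Counting error on 1 kb of transcript gives 95% intervals of 0.189 to 0.487 for the ARP1 ratio and 0.981 to 1.62 for the H929 ratio. YTHDF2 thus goes against the label of the H929 knockdown library, and every direction drawn from that library below rests on its label.

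Among the followed genes, STAT5A, a transcription factor of cytokine signalling, was higher in both libraries labelled knockdown. Its level was 1.35 FPKM in wild-type ARP1 and 6.45 in ARP1 knockdown, and 0.496 against 4.07 in H929. The log2 ratios were 1.66 and 1.76, with an adjusted p of 0.127 in limma. EGR1, an early growth response factor downstream of ERK, was lower in both, with 9.40 and 4.04 FPKM in ARP1 and 49.0 and 22.0 in H929 (adjusted p = 0.287). MAP2K2, which encodes the kinase MEK2, had log2 ratios of -0.33 in ARP1 and 0.20 in H929. CDKN1A, which encodes the CDK inhibitor p21, had log2 ratios of -1.24 and 0.15.

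**Figure D1:**
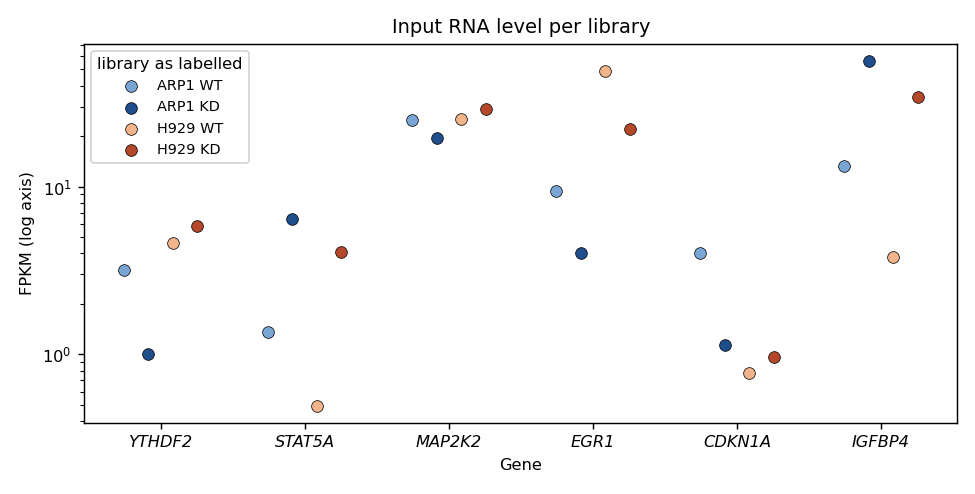
FPKM (log axis) of YTHDF2, STAT5A, MAP2K2, EGR1, CDKN1A and IGFBP4 in the 4 input libraries, each point being 1 library with no replicate. YTHDF2 stands at 31.6% of wild type in ARP1 knockdown and at 5.80 FPKM in the library labelled H929 knockdown.

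The library labelled H929 knockdown stood apart in the genes that distinguish the wild-type lines. Of protein-coding genes, 17 were at least 32-fold higher in wild-type ARP1 than in wild-type H929. They included HLA-DRA, an MHC class II chain, S100A4, a calcium-binding protein, ICAM3, an adhesion molecule, and MGMT, a DNA repair protein. HLA-DRA stood at 184 FPKM in wild-type ARP1, 190 in ARP1 knockdown, 2.32 in wild-type H929 and 67.8 in the library labelled H929 knockdown. S100A4 stood at 91.3, 172, 1.99 and 35.0 FPKM in the same order. The gain over wild-type H929 was divided by the difference between wild-type ARP1 and wild-type H929. The median of this share over the 17 genes was 37.0% (95% bootstrap interval 27.1% to 59.6%), and 16 genes were above 5%. With ARP1 knockdown in place of wild-type ARP1 the median share was 40.8% (28.7% to 55.4%). In the opposite direction 3 protein-coding genes were specific to H929, and their median share in ARP1 knockdown, measured in the same way, was 0.221% (-0.129% to 3.12%). With 3 genes these limits are only the lowest and the highest gene.

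**Figure D2:**
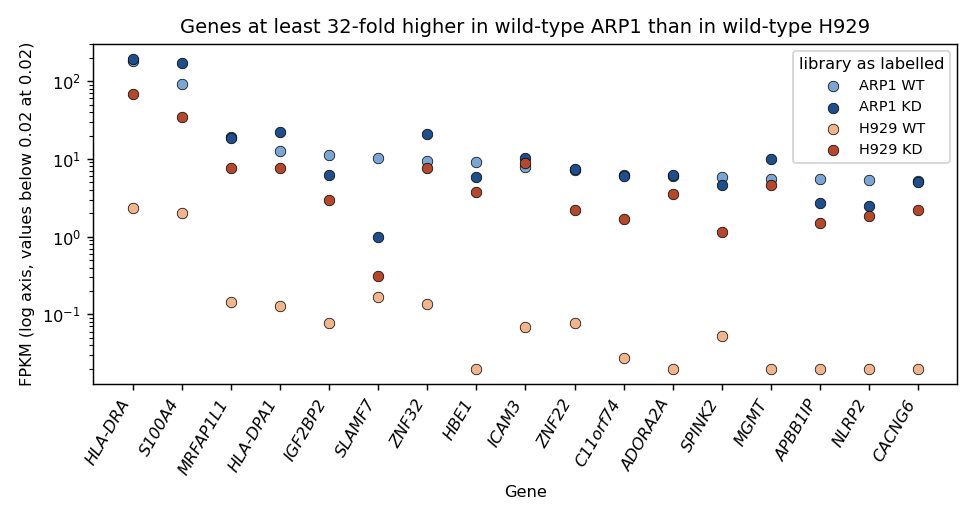
FPKM (log axis) of the 17 protein-coding genes at least 32-fold higher in wild-type ARP1 than in wild-type H929, with 1 point per library. In the library labelled H929 knockdown all 17 lie above wild-type H929, and their median gain is 37.0% of the difference between the wild-type lines.

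Across both lines, knockdown against wild type gave large and similar log2 ratios for a small set of genes, few of which passed the test. IGFBP4, which binds insulin-like growth factors, stood at 13.4 and 56.0 FPKM in wild-type and knockdown ARP1 and at 3.82 and 34.4 in H929. ID3, an inhibitor of basic helix-loop-helix factors, had log2 ratios of 1.39 and 1.49, and RNF185, an ER-associated ubiquitin ligase, of 1.67 and 1.60. EFNA4, an ephrin ligand, the glycolytic enzyme gene ALDOC and the nucleotide-hydrolysing DCTPP1 were also higher in both, with ratios between 0.91 and 1.44. Lower in both were LZTFL1, a regulator of ciliary trafficking (12.3 and 2.27 FPKM in ARP1, 11.9 and 2.22 in H929), the actin-sequestering TMSB4X (-1.44 and -1.47) and the ER chaperone gene HSP90B1 (-1.52 and -1.38). CD38, a plasma cell surface enzyme, the thrombin receptor gene F2R, SEL1L, part of an ER degradation complex, and HRASLS2 lay between -1.18 and -1.03. Adjusted p-values of these genes were 0.109 to 0.287.

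The limma test called 2 genes at 5%, 1 in each direction, and 1687 genes had an unadjusted p under 0.05. PTGES3L-AARSD1, a readthrough gene on chromosome 17, fell by 4.38 in ARP1 and by 3.85 in H929 (adjusted p = 0.0181), from 21.5 to 0.0787 FPKM and from 15.6 to 0.156. AARSD1, which shares that locus, was higher by 1.94 and 1.82. AL132780.3, which overlaps AJUBA and HAUS4 on chromosome 14, was listed at 0 in both wild-type libraries and at 39.2 and 27.0 FPKM in the knockdown libraries (adjusted p = 0.0116). TMEM189-UBE2V1, a further readthrough gene, had log2 ratios of 1.76 and 2.43. Fragments of these loci can be assigned to more than 1 gene, so their values are uncertain. The count of calls was 10 among genes with a mean of at least 5 FPKM and 14 after quantile normalization. It was 0 without a filter, where 2284 genes had an unadjusted p under 0.05.

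The lists of cytosolic ribosomal proteins and of glycolysis and hypoxia had higher medians in both knockdown libraries, and that of oxidative phosphorylation mainly in ARP1. They were called in camera at the preset correlation between genes. Of 85 measured cytosolic ribosomal protein genes, 64 were higher in both lines and 2 lower in both, with median log2 ratios of 0.45 in ARP1 and 0.23 in H929. Random lists matched on expression were also above 0, with medians of 0.19 and 0.09. RPL39L had ratios of 0.74 and 0.76, RPLP1 of 0.66 and 0.54, and RPS3 of 0.68 and 0.51. No member passed the test on its own. Of 43 nuclear genes of oxidative phosphorylation, 25 were higher in both lines, with medians of 0.34 and 0.07. The H929 median stood at percentile 62.7 of matched random lists, whose own median was 0.05. COX5B had ratios of 0.70 and 0.40, and NDUFA6 of 1.29 and 0.05, and after subtraction of the ARP1 knockdown share their H929 ratios were -0.24 and -3.10. Of 24 genes of glycolysis and the hypoxia response, 18 were higher in both, with medians of 0.22 and 0.16. ALDOC (1.08 and 1.06), PFKFB4 (1.12 and 0.48) and ALDOA (0.49 and 0.56) were among them. In camera with a preset correlation these lists had adjusted p-values of 6.65e-20, 3.27e-06 and 1.62e-05. With an estimated correlation the adjusted p = 0.657 for each. That test has 1 residual degree of freedom and decides little. For glycolysis and hypoxia the estimated correlation was only 0.0217, yet the unadjusted p in camera went from 1.79e-06 to 0.145.

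The list of the unfolded protein response and ER folding had lower medians in both lines, and it was called in camera at the preset correlation. Of 32 measured genes of the unfolded protein response and ER folding, 21 were lower in both lines and 1 was higher in both, with medians of -0.70 in ARP1 and -0.44 in H929. HSPA5, the main ER chaperone, went from 107 to 52.7 FPKM in ARP1 and from 192 to 93.9 in H929. HYOU1, another ER chaperone, had log2 ratios of -1.51 and -0.47. The camera test gave an adjusted p of 6.07e-05, and adjusted p = 0.657 with an estimated correlation. No member passed over all genes tested, and 7 passed when adjusted over the list alone. All 10000 random lists had a higher median in each line.

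The plasma cell identity list, with 18 measured members, had medians of -0.66 in ARP1 and -0.03 in H929, and 10 members were lower in both lines. The H929 median lay above that of all genes (-0.09). SLAMF7, a surface receptor of plasma cells, stood at 10.2 FPKM in wild-type ARP1 and 0.978 in ARP1 knockdown, and at 0.166 and 0.312 in H929. POU2AF1, a B-lineage coactivator, had log2 ratios of -1.50 and -0.30, and the integrin gene ITGA4 of -0.59 and -1.17. Camera gave an adjusted p of 0.0247, and 1 member passed when adjusted over the list alone. With an estimated correlation the adjusted p = 0.657, and with a pseudocount of 0.1 it was 0.0759. The H929 median stood at percentile 37.4 of the random lists. SLAMF7 is itself specific to ARP1, and its share in the library labelled H929 knockdown was 1.45% with wild-type ARP1 and 18.0% with ARP1 knockdown as the source.

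Genes of G2 and mitosis, 29 measured, had medians of -0.14 in ARP1, where the median of all genes was also -0.14, and -0.56 in H929, and 18 were lower in both. KIF11, a mitotic kinesin, had ratios of -0.83 and -0.92, TOP2A of -0.80 and -0.81, and ANLN of -0.51 and -1.06. Of 38 mRNA decay genes, 26 were lower in both, among them CNOT1, the scaffold of the deadenylase complex (-0.68 and -0.49), and UPF2 (-0.86 and -0.61), while BTG2 had ratios of 0.30 and 1.48. Of 16 genes driven by ERK signalling, 10 were lower in both, among them DUSP5 (-1.63 and -0.88) and ETV5 (-1.07 and -0.53). Adjusted p-values in camera were 0.0176, 0.0299 and 0.0416, and adjusted p = 0.657 for each with an estimated correlation. Mitotic genes also lost the call after subtraction of the wild-type ARP1 share (0.0718). Decay genes lost it at a mean of 5 FPKM (0.552) and after subtraction of the ARP1 knockdown share (0.0739). ERK-driven genes lost it with a pseudocount of 0.1 (0.0839) and after subtraction of the wild-type (0.199) or knockdown (0.425) share.

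The NF-kB target list was higher by camera (adjusted p = 0.00301), with 13 measured members and medians of -0.15 in ARP1 and 0.41 in H929. It was not called with an estimated correlation (adjusted p = 0.657). Of the 13 members, 6 were higher in both lines and 2 lower in both. Among those higher in both, CXCL10 had ratios of 0.42 and 1.06, CCL3 of 1.03 and 0.41, and CD83 of 0.92 and 0.40. B cell genes that plasma cells lose, 6 measured, had medians of -0.18 and 1.5 (adjusted p = 0.0327), led by HLA-DRA and HLA-DPA1, both specific to ARP1. With the ARP1 knockdown share subtracted from the library labelled H929 knockdown, an alternative chosen after seeing the data, this list was no longer called (adjusted p = 0.434), nor was it after subtraction of the wild-type share (0.656), rescaling by median of ratios (0.0661) or with a pseudocount of 0.1 (0.0584). With an estimated correlation its adjusted p = 0.657.

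Lists tied to the m6A pathway were not called over all genes tested. The 10 measured m6A writers had medians of -0.35 and -0.19 (adjusted p = 0.214), with ZC3H13 at -0.88 and -0.44. The 15 erasers and other readers had medians of -0.28 and -0.16 (adjusted p = 0.376), with FTO at -0.64 and -0.46 and IGF2BP2 at -0.76 and 1.87. IGF2BP2 is specific to ARP1, and its H929 ratio was -0.11 and 0.62 after subtraction of the wild-type and knockdown ARP1 share. The value of -0.11 is a floor, since the subtraction left no expression. The 32 measured transcripts reported to carry m6A or bind YTHDF2 had medians of -0.39 and -0.11 (adjusted p = 0.219). Among genes with a mean of at least 5 FPKM, 18 of its members were measured and the list was called lower (adjusted p = 0.0139); over its other alternatives the adjusted p ranged from 0.162 to 0.657. STAT5A, MAP2K2, EGR1 and CDKN1A stand in that list because published work on myeloma followed them, so they are not independent evidence of its direction.

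**Figure D3:**
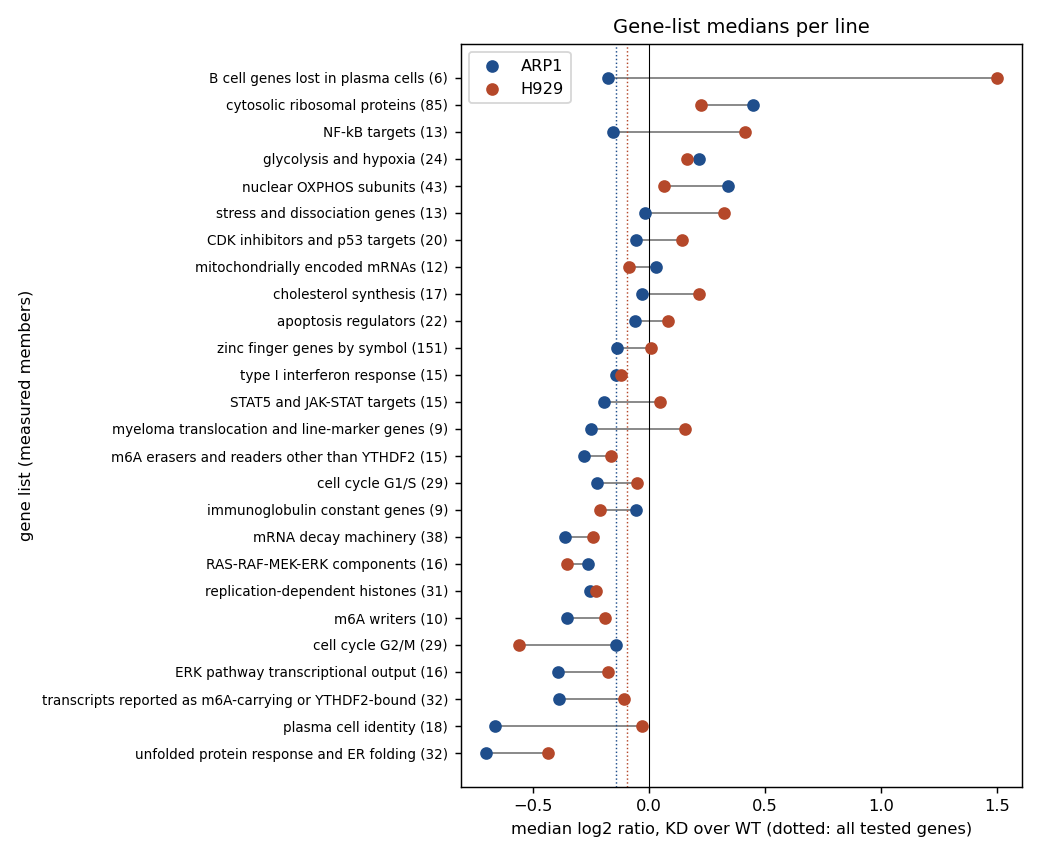
Median log2 ratio of knockdown over wild type, on the FPKM + 1 scale, for each list with at least 6 measured members, with ARP1 and H929 as separate points. Ribosomal protein genes lie at 0.45 and 0.23, and genes of ER folding at -0.70 and -0.44.

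In ARP1 alone, 103 genes were at 2-fold or more higher and 235 lower in knockdown. The highest protein-coding genes were HNRNPA1L2 (0.769 and 9.32 FPKM in wild type and knockdown), IGFBP4, AARSD1, TMEM189-UBE2V1 and RNF185. HNRNPA1L2 is a near copy of HNRNPA1, so its value is uncertain. The lowest were PTGES3L-AARSD1, PGRMC2, a haem-binding membrane protein (log2 ratio -2.27), the readthrough gene TGIF2-C20orf24 (22.2 and 3.97), the aspartic protease gene NAPSA (20.4 and 3.85) and FBXO41 (9.68 and 1.57). The 9 measured translocation and line-marker genes of myeloma were not called (camera adjusted p = 0.883), and their ARP1 median of -0.25 stood at percentile 11.6 of random lists. Of these, CCND2 stood at a log2 ratio of -1.19, ITGB7 at 342 and 142 FPKM, IRF4 at 187 and 90.7 FPKM, and MAF at 36.2 and 21.3. IL6R, the receptor of a myeloma growth factor, stood at 13.5 and 3.24 FPKM. The median gene of ARP1 had a log2 ratio of -0.14 on the deposited scale and -0.01 after median-of-ratios rescaling, which gave 181 higher and 152 lower.

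In H929 alone, 190 genes were at 2-fold or more higher and 181 lower in the library labelled knockdown. The median gene had a ratio of -0.09, and after median-of-ratios rescaling, which put it at 0.01, the counts were 238 and 129. After subtraction of the wild-type ARP1 share they were 192 and 1284, and of the knockdown share 151 and 616. The highest were HLA-DRA, TOMM6, S100A4, ICAM3 and HLA-DPA1. TOMM6, a subunit of the mitochondrial import pore, stood at 18.9 FPKM in wild type and 266 in the library labelled knockdown, and at 353 in wild-type ARP1. PIM1, a kinase induced by STAT5, stood at 5.15 and 16.4 FPKM. The lowest after PTGES3L-AARSD1 were the phosphatase gene PDXP (37.9 and 3.36 FPKM), SELENOF (21.6 and 4.02), LZTFL1 (11.9 and 2.22) and the sulphotransferase gene CHST11 (9.57 and 2.02).

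Set against each other, the lines shared 18 genes at 2-fold or more higher and 28 lower, where independent lists would share 1.82 and 3.97. Another 14 genes went opposite ways, and the number that independent lists would give for these was not computed. Of the shared genes, 12 higher and 16 lower were annotated as protein coding. The others were small RNA genes or genes of unmatched type. After median-of-ratios rescaling 31 were higher and 17 lower in both. Across the 10724 genes tested, which are not independent replicates, Pearson's correlation of the log2 ratios was 0.28 and Spearman's 0.33. With the ARP1 knockdown share subtracted from the library labelled H929 knockdown, Pearson's correlation was 0.0187, and 13 genes were higher and 22 lower in both, where independent lists would share 1.43 and 13.6. More genes, 45, then went opposite ways. Subtracting ARP1 knockdown values itself lowers the H929 ratio of genes high in ARP1 knockdown. IGFBP4 then had an H929 ratio of 2.09, STAT5A of 1.20, HSP90B1 of -1.28, CD38 of -1.18 and LZTFL1 of -2.02. EGR1 stood at -0.50, EFNA4 at 0.29 and HYOU1 at 0.01. ZNF32 (-0.18) and S100A4 (-1.58), higher in both lines as deposited, were left with no expression by the subtraction. Their values are therefore floors and not estimates.

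**Figure D4:**
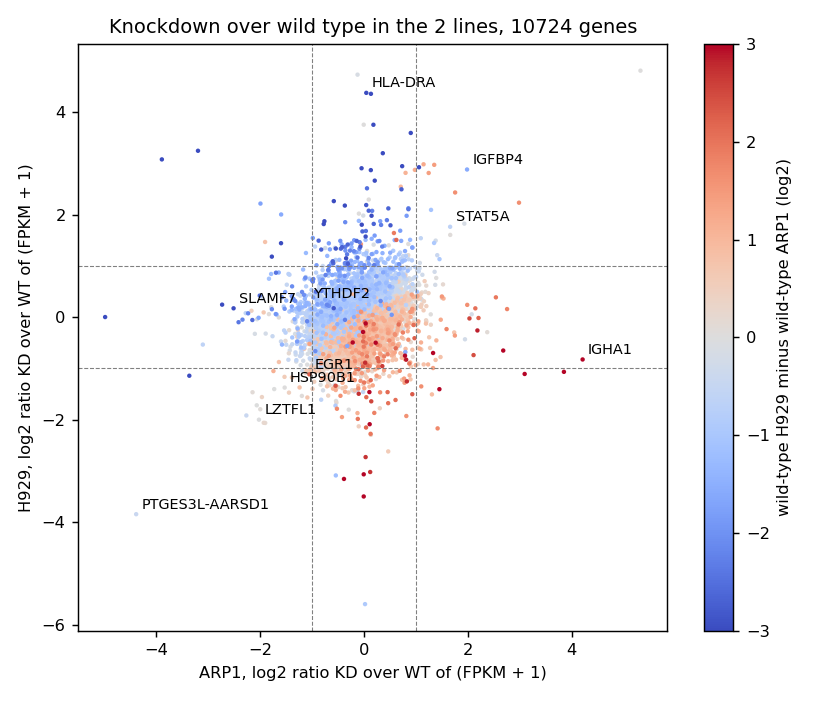
Log2 ratio of knockdown over wild type in ARP1 (horizontal) and H929 (vertical), on the FPKM + 1 scale, for all genes tested, coloured by the difference of wild-type H929 from wild-type ARP1. Dashed lines mark 2-fold, and Pearson's correlation across genes is 0.28.

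H929 differed from ARP1 by more genes than knockdown did from wild type in most settings, and this comparison gives the scale for the others. Higher in H929 at 5% were PIK3R2, a regulatory subunit of PI3 kinase (0.129 FPKM in ARP1 knockdown and 13.1 in wild-type H929, adjusted p = 0.0227), MAGEA6, a cancer-testis antigen (1.15 and 21.8 in wild type, adjusted p = 0.0227), TP53INP2 (0.0918 in wild-type ARP1 and 6.36 in the library labelled H929 knockdown, adjusted p = 0.0281) and the immunoglobulin constant gene IGHA2 (3.60 and 110 in wild type, adjusted p = 0.0227). These 4 were the calls, and 1987 genes had an unadjusted p under 0.05. IGHA2 is a near copy of IGHA1, which stood at 4841 FPKM in wild-type H929, so its value is uncertain. The chemoattractant receptor gene GPR15 (0.493 and 84.1 FPKM), the integrin gene ITGAL (3.40 and 22.8), EGR1 and the protease gene FURIN (3.31 times the ARP1 level in wild type) were also higher in H929 without passing. Lower in H929 without passing were S100A4, HLA-DRA, HLA-DPA1, MRPL34 (29.9 and 8.19) and DEPTOR, an mTOR inhibitor (21.2 and 1.73). The test averages over both genotypes, so the library labelled H929 knockdown counts in it. There HLA-DRA (67.8 FPKM) and S100A4 (35.0) lay between the wild-type lines, which lowers their fitted line difference. Comparing wild-type libraries alone, 316 genes were at 2-fold or more higher and 461 lower in H929. Counts of calls ranged from 0 without a filter to 53 at a mean of 5 FPKM over changes of filter and scaling, and the model without the block gave 20. Subtraction of the wild-type or knockdown ARP1 share from the library labelled H929 knockdown, which itself sets the lines apart, gave 833 and 211.

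By camera, genes driven by ERK were higher in H929 (16 measured, adjusted p = 0.00197). Ribosomal protein genes (5.66e-07), replication-dependent histones (5.70e-06), B cell genes (0.00223) and CDK inhibitors with p53 targets (0.0380) were lower. With an estimated correlation the adjusted p = 0.884 for each. The CDK inhibitor list also lost the call with a pseudocount of 0.1 (0.0547) and at a mean of 5 FPKM (0.0712), and over its alternatives the adjusted p ranged from 0.0120 to 0.884.

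Immunoglobulin genes separated the lines by heavy chain, while the same kappa variable gene dominated in all 4 libraries. IGHA1 stood at 4.17 FPKM in wild-type ARP1, 94.9 in ARP1 knockdown, 4841 in wild-type H929 and 2728 in the library labelled H929 knockdown. The kappa constant gene IGKC lay between 6627 FPKM, in wild-type H929, and 18590 FPKM, in wild-type ARP1, over the 4 libraries. The kappa variable gene IGKV1-6 held 99.2% to 99.8% of kappa variable FPKM in each library. NCI-H929 is described as carrying a translocation that brings FGFR3 and NSD2 under immunoglobulin control. FGFR3 stood at 0.325 FPKM in wild-type ARP1 and 0.668 in wild-type H929, and NSD2 at 6.35 and 7.25. Whether the line labelled H929 is NCI-H929 was not tested and stays open with these values, so differences from ARP1 refer to the label.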

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

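The tests of swapped labels, of the source of the ARP1 material and of the changes shared by both lines were chosen after the results were seen. No group held 4 samples, so no sample was set apart from its own group. The results in this part are genes and lists named in the text whose log2 ratios had opposite signs in the lines, each by at least 0.1; these differences were not tested, since each line had 1 library per genotype. Each value is the ARP1 ratio minus the H929 ratio.

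YTHDF2 differed by -1.33, MAP2K2 by -0.53 and CDKN1A by -1.39. SLAMF7 differed by -2.68, IL6R by -1.92, CCND2 by -1.68, IRF4 by -1.19, IGKC by -1.45 and IGF2BP2 by -2.63. SELENOF differed by 3.59, GPR15 by 2.86, IGHA1 by 5.04, IGHA2 by 0.73 and IGHV1-69 by 4.21, and IGKV1-6 differed by -1.38. Some of these signs moved with the subtraction of an ARP1 share: of the 15 genes, 6 kept opposite signs after subtraction of the wild-type ARP1 share and 13 after that of the knockdown share. With the wild-type share the H929 ratio of SLAMF7 was -0.22, of IL6R -1.77, of IRF4 -0.97 and of IGF2BP2 -0.11, and with the knockdown share that of IGHA2 was 0.21. The values of SLAMF7, IL6R and IGF2BP2 are floors, since the subtraction left these genes with no expression. Of the lists, NF-kB targets differed by -0.57, myeloma translocation and line-marker genes by -0.40 and B cell genes lost in plasma cells by -1.68.

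The first pattern is that YTHDF2 was not lower in the library labelled H929 knockdown. Library scaling is argued against: the lowest H929 log2 ratio of YTHDF2 was 0.38 over median-of-ratios rescaling and quantile normalization. If the H929 labels were swapped in unmixed libraries, genes higher in ARP1 knockdown would be lower in the library labelled H929 knockdown. The medians of genes 2-fold higher and 2-fold lower in ARP1 differed by 0.32 instead (95% bootstrap interval 0.13 to 0.57), but with 40.8% ARP1 knockdown material in that library a modelled swap gives from 0.57, if H929 shares none of the ARP1 log2 change, to -0.86, if it shares all of it. How much H929 shares is not known, so a swap cannot be told apart. ARP1 material cannot lift YTHDF2 above its wild-type H929 level of 4.62 FPKM. The gene stood at 3.17 FPKM in wild-type ARP1 and lower still in ARP1 knockdown. After subtraction of the wild-type and knockdown ARP1 share its H929 log2 ratio went from 0.28 to 0.57 and 0.85. Such a mix thus widens the conflict with the label, and a lost knockdown alone gives no rise over wild type. These ratios have no interval, so a knockdown lost from the H929 cells stays open and untested.

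The second pattern is that genes specific to ARP1 sat at intermediate levels in the library labelled H929 knockdown. If cells or RNA of ARP1 were in it, their median share would lie within 2-fold of the 43.7% that the level of IGHA1 implies. The share was 37.0% (27.1% to 59.6%), so ARP1 material may be present. Single genes ranged from 1.45% (SLAMF7) to 113% (ICAM3) with wild-type ARP1 as the source. With ARP1 knockdown as the source they ranged from 18.0% (SLAMF7) to 84.8% (ICAM3). A mix with no other change would give about the same share for every gene. The share subtracted from all genes is thus a median over unlike values. The 3 genes specific to H929 kept a median of 79.5% of their wild-type level, from 37.0% in the lowest to 91.1% in the highest. That median is more than the 56.3% of IGHA1, and a range over 3 genes decides nothing, so these 3 genes add nothing for ARP1 material. Across the 17 genes the log2 share followed the ARP1 knockdown over wild-type ratio with a slope of 1.12 (0.43 to 1.37), and 0.66 (0.32 to 1.08) without SLAMF7. Both quantities hold the wild-type ARP1 level in their divisor, which can itself give a positive slope. The slope therefore cannot decide whether wild-type or knockdown ARP1 is the source. For H929 material in ARP1 knockdown, the median share over 3 genes was 0.221% (lowest -0.129%, highest 3.12%) against 1.88% for IGHA1. Over 11 genes of all types it was 0.562% (0.000494% to 4.52%). The range of the 3 and the interval of the 11 hold the IGHA1 value while reaching near or below 0, which leaves this open.

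The third pattern is the set of changes shared by the knockdown libraries. Over 338 genes at 2-fold or more in ARP1, the H929 log2 ratio in the ARP1 direction had a median of 0.16. A mix with 40.8% ARP1 knockdown material gave 0.26. The median difference was -0.0510 (-0.105 to -0.00723), an interval that leaves out 0, so the mix gave somewhat more than was seen. Over the 138 with similar wild-type levels the difference was 0.04 (-0.05 to 0.10). Whether the typical shared change comes from such a mix thus cannot be told. The 18 genes 2-fold higher in both lines lay within simulated mixes at that share (10 to 18 in 95% of 1000). The share was estimated anew under each scaling. After median-of-ratios rescaling the 31 lay within mixes at 39.5% (23 to 35). After quantile normalization the 35 lay above mixes at 38.1% (18 to 29). The 28 lower in both lay above mixes at 40.8% (3 to 13) by more than their counting error (18.6 to 40.5). So did the 17 (9.90 to 27.2) and 19 (11.4 to 29.7) under these scalings, where mixes gave 0 to 7 each. At the upper bounds of the share, 55.4%, 53.6% and 56.6%, mixes gave 11 to 27, 5 to 15 and 6 to 17. The 28, 17 and 19 lay above these by less than their counting error. For the genes lower in both, a mix at the estimated share is thus argued against as the whole cause. Such a mix cannot be told apart at the upper bound, nor for the genes higher in both. Reassignment between genes that overlap by position is argued against as the whole cause, since 30 of the 46 (65.2%) overlapped no other measured gene. This share is near the background of 68.4%. Several of the 30 are small nuclear RNA genes, and moves of fragments between near-identical gene copies were not tested. A shared batch cannot be told apart from the knockdown (correlation between lines 0.28), because each genotype has 1 library per line.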

How the results depend on the processing

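Alternatives that subtract an ARP1 share, keep genes with similar wild-type levels or split the libraries otherwise were chosen after seeing the data. Where a cause is not named, the cause was not tested. Knockdown against wild type called 2 genes in limma, and also 2 with each other pseudocount, median-of-ratios rescaling, no trend and no replicate block. It called 0 without a filter (2284 at an unadjusted p under 0.05), 10 at a mean of 5 FPKM, 14 after quantile normalization, 106 and 4 after subtraction of a wild-type and a knockdown ARP1 share, and 389 among genes with wild-type levels within 0.5. That last choice selects genes by the same libraries and shrinks the residual. The other split within lines, ARP1 knockdown and wild-type H929 against the rest, is the one that swapped H929 labels would give. It called 26 genes against 2 for the labelled split, and had 247 genes against 1687 at an unadjusted p under 0.05. These counts point opposite ways and rest on 1 residual degree of freedom, so they decide nothing about a swap. The line comparison called 4 genes and moved to 0 without a filter, 53 at 5 FPKM, 21 after median-of-ratios rescaling, 45 after quantile normalization, 20 with no replicate block, and 833 and 211 after subtraction of the wild-type and knockdown ARP1 share.

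The 338 genes at 2-fold in ARP1 became 808 and 512 at pseudocounts of 0.1 and 0.5, 170 at 5 FPKM, 1908 at 1.5-fold and 37 at 4-fold. The 371 genes in H929 became 872, 564, 188, 1771 and 57, and 1476 and 767 after the wild-type and knockdown ARP1 subtraction and 87 among genes with similar wild-type levels. The 46 genes shared by both lines became 136, 71, 28 and 409 at 1.5-fold, 135 and 35 after the wild-type and knockdown subtraction and 24 among similar genes. The correlation across genes, 0.28, was 0.48 and 0.0187 after the wild-type and knockdown subtraction and 0.49 among similar genes. The H929 ratio of YTHDF2 was 0.85 after the knockdown subtraction, and no setting brought it below 0. Of the 10 lists called, 0 were called with an estimated correlation, where the test has 1 residual degree of freedom and could hardly call any.

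Fitted ratios of named genes turned sign for 7 of 82 after subtraction of the wild-type ARP1 share and for 11 of 83 after that of the knockdown share, among them HLA-DRA, which went from 2.21 to -0.84 in both. With the knockdown share S100A4 went from 2.25 to -0.34, NDUFA6 from 0.67 to -0.90, DEPTOR from 1.06 to -0.55 and MRPL34 from 0.32 to -1.36. For HLA-DRA, S100A4 and MRPL34 the subtraction left no expression in the library labelled H929 knockdown. Their turned signs rest on that floor and are not measured reversals. Median-of-ratios rescaling turned 3, quantile normalization 2 and a pseudocount of 0.1 turned 1. None of the genes that turned was called for knockdown before or after. Subtraction of the wild-type ARP1 share brought 22 of 82 named genes past the threshold, and of the knockdown share 0 of 83. Leaving out a line leaves no residual degree of freedom, so single-line counts stand in its place. The alternatives with immunoprecipitation libraries were not run. The depth, about 25 fragments per kb at 1 FPKM, limits genes near the filter.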

Other observations

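The KEGG tests in this part were chosen after the data were seen. Of 254 KEGG pathways in the deposited annotation, camera with a preset correlation called 13 for knockdown against wild type, 10 higher and 3 lower. Protein processing in the endoplasmic reticulum, with 143 measured genes, was lower (medians -0.34 in ARP1 and -0.22 in H929, adjusted p = 0.0136). N-glycan biosynthesis, with 39 genes, was also lower (-0.43 and -0.16, adjusted p = 0.0425). The ribosome pathway was higher (129 genes, 0.38 and 0.20, adjusted p = 2.06e-16), as was oxidative phosphorylation (106 genes, 0.30 and 0.03, adjusted p = 0.000116). With an estimated correlation the smallest adjusted p = 0.859, so none was called, in a test that could hardly call any.

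The lists of other cell types were thinly measured. The T and NK cell list had 1 measured member and summed to 4.39, 6.96, 4.48 and 5.27 FPKM in wild-type ARP1, ARP1 knockdown, wild-type H929 and the library labelled H929 knockdown. The myeloid and erythroid list had 2 and summed to between 25.03 and 29.1 FPKM, and the epithelial and stromal list had 3, with medians of 0.52 and 0.07. The 12 mitochondrially encoded mRNAs had medians of 0.03 and -0.09, and the 151 zinc finger genes of -0.14 and 0.01. Medians were -0.14 and -0.12 for 15 interferon response genes, -0.06 and 0.08 for 22 apoptosis regulators, -0.03 and 0.22 for 17 cholesterol synthesis genes, -0.02 and 0.32 for 13 stress genes, -0.26 and -0.35 for 16 RAS to ERK components, and -0.22 and -0.05 for 29 G1/S genes. They were -0.06 and 0.14 for 20 CDK inhibitors and p53 targets, -0.19 and 0.05 for 15 JAK-STAT genes, -0.25 and -0.23 for 31 histones -0.25 and 0.15 for 9 translocation and line-marker genes, and -0.06 and -0.21 for 9 immunoglobulin constant genes. None of these lists was called for knockdown against wild type over all genes tested. Histones were called lower after subtraction of the wild-type (adjusted p = 0.0488) and of the knockdown ARP1 share (0.0118), and over all settings their adjusted p ranged from 0.0118 to 0.924.

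The heavy chain variable gene IGHV1-69 stood at 0.183 FPKM in wild-type ARP1, 9.13 in ARP1 knockdown, 567 in wild-type H929 and 262 in the library labelled H929 knockdown. HLA-DRA in wild-type H929 was 1.26% of its wild-type ARP1 level.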
